A study of Ogataea parapolymorpha with 2 samples.

How the data were processed

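The series holds 2 RNA-seq libraries of Ogataea parapolymorpha DL-1, 1 untreated and 1 given caffeine at 20 mM for 2 h, and each library formed its own group, by its title or its treatment label. Per the labels' protocols, RNA was extracted with hot phenol, and stranded mRNA libraries were sequenced as paired reads of 100 bases on an Illumina instrument. Per the submitters' processing notes, Bowtie2 was used; its version, the counting tool, the genome build and the annotation are not given in the sources used here, nor whether counting used strand. Reads of near-identical or overlapping genes could therefore have been shared in a way that was not checked.

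The authors deposited 4 gene tables with 5408 features each: raw read counts per gene, RPKM values, and the counts scaled by relative log expression (RLE) and by TMM. In the deposited RLE and TMM tables, whose values are a scaled signal, every value equalled the raw count times 1 constant per library within a tolerance of 0.0051 plus 1e-06 of the count, with constants of 1.042 and 0.959 for RLE and 1.039 and 0.964 for TMM (untreated and caffeine-treated). The deposited RPKM values, named so per the file headers, corresponded to counts divided by the column total and by a length shorter than the listed one by 176.8 bases in the untreated and 172.4 bases in the caffeine-treated library, within 1 base for 90.1% and 90.7% of genes with more than 500 counts. How those lengths were set is not stated. A summary sheet of quartiles was not used.

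All 5408 locus tags matched a RefSeq gene table of assembly Hansenula_2, which gave 5325 protein-coding genes, 80 tRNA and 3 rRNA features. The 83 RNA features had 0 reads in both libraries and entered no comparison. That table was used only for gene type and for which genes neighbour each other. It holds no symbols apart from the locus tags, and the product column of the deposited tables is empty. For this reason 38 lists of gene symbols fixed before the data were examined could not be matched. In their place, 34 lists were built from 377 COG identifiers in the deposited tables, after the annotation columns had been seen and before any fold was computed. COG functions were supplied from general knowledge, and those of some single genes named in the text were added after their folds were seen. A COG can hold several proteins of different function, so each name describes a group. The lists held 736 of the compared genes. Of the 4861 compared genes 2176 had a COG, 2136 only a NOG identifier, whose function is not named here, and 549 neither.

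Raw counts were scaled by TMM with edgeR 4.0.16 in R 4.3.3, which gave effective totals of 17788292 and 19186645 reads. Genes with at least 10 CPM in either library were kept. The measure was the log2 ratio of scaled counts, caffeine-treated over untreated, with a count of 0 set to a floor of 3 counts (0.156 CPM in the untreated and 0.169 CPM in the caffeine-treated library). One protein-coding gene had 0 counts in the caffeine-treated library and none had 0 in the untreated library. With 1 library per group neither edgeR nor DESeq2 was used for a test, and genes were counted by a size rule of 2-fold, with 4-fold beside it. Intervals are exact 95% Clopper-Pearson intervals of the caffeine-treated share of a gene's counts, turned into a ratio. PCR reads without molecular identifiers are not independent molecules, so that intervals and floors cover counting error only and leave out the variation between cultures. The median interval reached 0.85 log2 units to either side for genes whose smaller count was 10 to 20, 0.29 for 100 to 200, 0.10 for 1000 to 2000 and 0.03 for 10000 to 20000.

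A list's median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 10 bins, and called outside when it fell beyond the central 95%, with the percentile rounded to its first decimal. That rounding was set after the results were seen and placed the D-amino acid oxidase list, which lay at the limit, inside. Lists with fewer than 4 genes were not placed. The rule for named genes was fixed before the data were examined: the 12 highest and 12 lowest log2 folds among genes with a functional description, up to 2 highest and 2 lowest members of each list described, and the genes of the cell wall integrity cascade. It also asked for the wall genes FKS1, CHS3 and GAS1 where present. A functional description was taken to be a COG outside the categories of unknown or only general function. The cascade genes and those wall genes carry no name in the tables, were not located and are not reported one by one. Any other gene named in the text is said to have been picked after its value was seen.

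The calculation was tested on simulated counts for 4772 genes drawn with Poisson error from the real means and totals. Of genes made 1.5-fold different 0% passed the 2-fold rule, of those made 3-, 4- and 8-fold different 100% passed, and 0 unchanged genes passed. Intervals held the true ratio for 95.0% of unchanged genes, and 2.5% of 200 random unchanged lists lay outside the central 95%. The simulation had no variation between cultures.

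Alternatives set before the data were examined were library totals, DESeq2 1.42.0 size factors and upper-quartile scaling, the deposited RPKM, RLE and TMM tables, no filter, a filter of 50 CPM, 5 CPM added to both libraries, a rule asking the whole counting interval to pass 2-fold, the 20 most abundant genes left out, and random lists not matched on expression. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.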

Results

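RNA was profiled from the thermotolerant methylotrophic yeast Ogataea parapolymorpha, named Hansenula polymorpha in the labels, strain DL-1. A culture was grown at 37 °C in rich glucose medium (YPD) to an optical density of 1.0 and divided. One part, harvested without the drug, gave the untreated library, and the other received 20 mM caffeine for 2 h, giving the caffeine-treated library. Caffeine is a purine analogue long used in yeast to stress the cell wall, and it inhibits the TOR kinase of budding yeast. The study's subject is the cell wall integrity pathway, the MAP kinase cascade that ends in Mpk1, and the comparison asks which transcripts differ after the drug. There was 1 library in each of the 2 groups. The untreated library held 19184978 counted reads and the caffeine-treated library 17789838. Of 5325 protein-coding genes, 4861 (91.3%) reached 10 CPM (counts scaled to a common library total) in at least 1 library and were compared.

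After caffeine, 9 of 28 genes listed under nitrogen uptake and amino acid transport, enzymes included, were at least 2-fold higher than without it. Of 23 glycolysis and fermentation genes, 14 were at least 2-fold lower. An ammonium transporter stood 33.5-fold higher, a log2 fold of 5.07 that became 4.46 with 5 CPM added to both libraries, while the most abundant hexokinase gene was 4.86-fold lower and a phosphofructokinase 5.15-fold lower. Enzymes of cell wall polysaccharides and their sugar precursors had a list median of 1.53-fold, with 20 of 24 genes within 2-fold. Cytosolic ribosomal protein genes of eukaryote and archaeal families had a median 1.40-fold lower, with 34 of 35 below 0 and 34 within 2-fold. In all, 346 genes were at least 2-fold higher in the caffeine-treated library and 256 at least 2-fold lower, and 4259 (87.6%) lay within 2-fold. At the 4-fold level these counts were 67 and 50.

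With 1 library per group these differences have no replicate check, and no test between conditions was made. Each gene is given below with its log2 fold of caffeine-treated over untreated, after scaling by trimmed mean of M values (TMM), followed by an exact 95% interval that covers counting error only. The labels do not say when the untreated part was harvested and describe no untreated part kept for the same 2 h, so that time in culture was not separated from caffeine. The share of genes past 2-fold that were higher was 57.5% with TMM and 76.3% when library totals were used instead, because that scaling adds 0.22 to every log2 fold. All folds below are relative to the TMM scaling, and a median between -0.22 and 0 turns positive with library totals. Intervals given for list medians are 95% order-statistic intervals over the members.

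Genes carry locus tags without symbols in the tables used, so each is named here by its orthologous group (COG) and that group's function. Members of the cascade itself, such as Mpk1 or its upstream kinases, were not located. Whether the signalling list holds any of them is not known. Lists of groups were compared with 10000 random lists of the same size and expression level, and the percentile of a list's median is given as a description of these 2 libraries. Of 34 lists, 3 had a median above the central 95% of their random lists and 7 a median below it. Chance alone would put about 1.7 outside if genes varied independently, which neighbouring genes did not.

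Glycolysis and fermentation showed the lowest median of all lists, a log2 fold of -1.04 over 23 genes (interval -1.70 to 0.42), below all 10000 random lists. Of its members 14 were at least 2-fold lower, 3 at least 2-fold higher and 6 within 2-fold. Lowest stood a gene of phosphofructokinase (COG0205), the enzyme of the committing step, at -2.37 (-2.39 to -2.34). The most abundant hexokinase gene (COG5026) went from 9545 to 1965 scaled CPM, a log2 fold of -2.28 (-2.30 to -2.26). Among members picked after their values were seen, the other phosphofructokinase gene stood at -2.06 (-2.09 to -2.03), pyruvate kinase (COG0469) at -1.70 (-1.72 to -1.69), enolase (COG0148) at -1.24 (-1.26 to -1.23) and glyceraldehyde-phosphate dehydrogenase (COG0057) at -1.18 (-1.19 to -1.17). Alcohol dehydrogenases went both ways. Of 6 zinc-dependent alcohol dehydrogenases (COG1064) 5 lay above 0, with a median of 0.72 at percentile 99.89 of random lists. The highest of them stood at 1.60 (1.54 to 1.66), while the most abundant, with 166540 untreated counts and likewise picked afterwards, stood at -1.85 (-1.87 to -1.84). The 3 members of the whole list that were at least 2-fold higher were 2 of these dehydrogenases and a hexokinase-group gene with 68 untreated counts at 1.76 (1.37 to 2.17). With library totals, 10 members in place of 14 were at least 2-fold lower.

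The tricarboxylic acid cycle and the glyoxylate list also had medians below their random lists, while other lists of central carbon metabolism lay inside. The tricarboxylic acid cycle list had a median of -0.47 over 21 genes (interval -0.96 to -0.10, percentile 2.1), with 18 genes below 0, or 14 with library totals, 4 genes at least 2-fold lower and none 2-fold higher. Its lowest members were a malate dehydrogenase (COG0039) at -1.68 (-1.72 to -1.64) and a dihydrolipoamide acyltransferase (COG0508) at -1.67 (-1.71 to -1.63), and its highest was fumarase (COG0114) at 0.55 (0.52 to 0.58). Genes of the glyoxylate cycle, gluconeogenesis and acetate use, which many yeasts induce when glucose runs out, had a median of -0.65 over 7 genes (interval -1.37 to -0.17, percentile 1.3). Phosphoenolpyruvate carboxykinase (COG1866) stood lowest there, at -1.37 (-1.42 to -1.33), and malate synthase (COG2225) highest, at -0.17 (-0.21 to -0.12), a sign that turns with library totals. Oxidative phosphorylation had a median of -0.18 (percentile 26.2), which turned to 0.03 with library totals, and the pentose phosphate pathway one of -0.28 (percentile 9.9). Methanol metabolism, the specialty of this yeast, had a median of 0.28 (percentile 95.2). No member was 2-fold higher and 1 was 2-fold lower, or 2 and 0 with library totals. Of its 12 members 4 were also in another list, as were 3 of the 12 pentose phosphate genes. The methanol list takes in whole groups, such as transketolases and lactate dehydrogenase-type oxidoreductases, so that its median need not describe methanol genes.

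Nitrogen uptake and amino acid transport had a median of 0.45 over 28 genes (interval -0.05 to 1.09, percentile 99.6), with 9 genes at least 2-fold higher, 2 at least 2-fold lower and 17 within 2-fold. An ammonium transporter (COG0004) went from 9.1 to 305 scaled CPM, a log2 fold of 5.07 (4.84 to 5.30). An amino acid transporter (COG0531) followed at 3.88 (3.59 to 4.18), or 3.06 with 5 CPM added to both libraries. Proline dehydrogenase (COG0506), the entry step of proline breakdown, was among the abundant members and stood at 2.10 (2.05 to 2.14). Nitrite reductase (COG1251) stood at 1.23. Both are enzymes, count among the 9 higher genes and were picked after their values were seen. The list did not move as a block, since an amino acid permease of the LysP type (COG0833) was at -3.07 (-3.17 to -2.97) and a sodium-solute symporter (COG0591), from the group that holds urea transporters, at -2.39 (-2.57 to -2.23). Among 12 genes of the D-amino acid and glycine oxidase group, 3 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.51 at the upper limit of its random lists. Nucleobase transport and purine breakdown, of interest because caffeine is itself a purine, had a median of -0.13 over 13 genes (percentile 19.8), with 7 genes below 0, or 5 with library totals. The list does not hold the purine nucleoside permease (COG5042) given further on at 3.83, nor, picked after its value was seen, a cytosine and guanine deaminase type gene (COG0402) at 2.32 (2.24 to 2.41). Within that list 2 permeases for purines and related bases (COG1953) stood at 2.06 (1.75 to 2.38) and 1.75 (1.63 to 1.87), and 2 adenosine deaminase type genes (COG1816) at -0.73 (-0.88 to -0.59) and -0.58 (-0.66 to -0.50). Amino acid biosynthesis as a list had a median of -0.16 over 67 genes, or 0.05 with library totals, inside the range of its random lists, although glutamate dehydrogenase (COG0334) stood at 1.87 (1.84 to 1.90) and an acetolactate synthase group gene (COG0028) at 2.33 (2.12 to 2.53). The lowest members of that list were a cysteine synthase type gene (COG0031) at -1.84 (-1.92 to -1.75) and the aromatic pathway's DAHP synthase (COG0722) at -1.47 (-1.52 to -1.42).

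**Figure D1:**
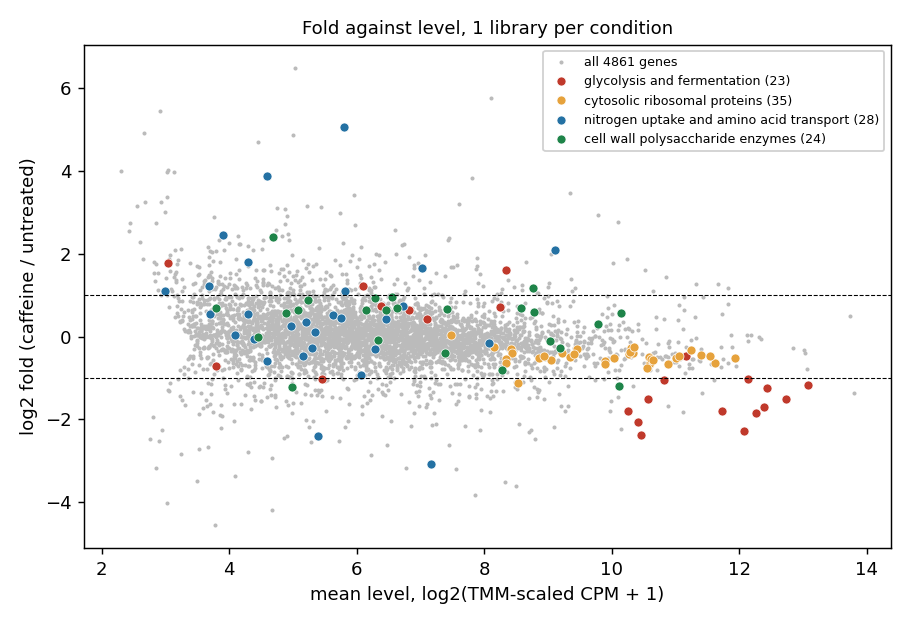
Each point is a gene, with its mean level in the 2 libraries on the horizontal axis, as log2 of TMM-scaled CPM plus 1, and its log2 fold of caffeine-treated over untreated on the vertical axis; dashed lines mark 2-fold and colours mark 4 lists. Most glycolysis genes at high levels lie below the lower dashed line, ribosomal protein genes form a band around -0.48, and nitrogen uptake genes spread from -3.07 to 5.07.

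Stress on the cell wall is the subject of the series. Enzymes that build or trim cell wall polysaccharides, or make their sugar precursors, had a median log2 fold of 0.61 over 24 genes. The interval of this median was -0.07 to 0.69, and the median lay above all 10000 random lists. The precursor groups are COG0449, COG1109 and COG4284. Of the 24 genes 16 lay above 0, 2 of these at least 2-fold higher, while 8 lay below 0, 2 of these at least 2-fold lower. With library totals 19 lay above 0 and 5 below, with 5 at least 2-fold higher and 0 lower. Of 3 glucanase genes of the Exg type (COG2730), 2 led the list at 2.41 (2.19 to 2.64) and 1.18 (1.13 to 1.23). At the other end stood a glycosyltransferase of cell wall biogenesis (COG1215) at -1.21 (-1.39 to -1.03) and a glucanase of the Scw and Bgl2 type (COG5309) at -1.18 (-1.21 to -1.15). The group COG1215 as a whole had a median of 0.66 over 5 genes (percentile 99.04), with 3 above 0 and 1 at least 2-fold lower. Protein mannosylation and N-glycosylation, which furnish the mannoproteins of the outer wall, had a median of -0.25 over 30 genes (interval -0.48 to 0.11, percentile 1.4), with 17 genes below 0, or 15 with library totals, 1 gene at least 2-fold higher and none 2-fold lower. Its lowest members were a protein O-mannosyltransferase (COG1928) at -0.98 (-1.03 to -0.94) and a nucleotide-sugar transporter of the Vrg4 type (COG5070) at -0.91 (-0.97 to -0.85). The highest were mannosyltransferases of the Ktr type (COG5020) at 1.15 (1.03 to 1.29) and of the Och1 type (COG3774) at 0.73 (0.64 to 0.82).

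Genes of the signalling list differed little, and whether they include the cascade is not known. The list of 48 protein kinases, phosphatases and other signalling proteins had a median of -0.06 (percentile 32.6), or 0.16 with library totals, and 47 members within 2-fold. The exception was a serine/threonine protein kinase (COG0515) at -1.63 (-1.77 to -1.50), and the highest member was a phosphatidylinositol-phosphate kinase of the Mss4 type (COG5253) at 0.96 (0.80 to 1.12). Cytoskeleton genes had a median of 0.16 over 29 genes (interval -0.08 to 0.41, percentile 98.0, or 88.9 among random lists not matched on expression), all within 2-fold, led by a septin (COG5019) at 0.95 (0.64 to 1.28) and a kinesin (COG5059) at 0.87 (0.72 to 1.02).

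Ribosomal protein genes lay close together. The list took cytosolic ribosomal proteins only from eukaryote and archaeal families. Of its 35 genes, 34 were below 0 under both TMM and library totals, and the median was -0.48 (interval -0.54 to -0.41, percentile 0.2). Only the L14e family gene at -1.13 (-1.18 to -1.08, COG2163) passed 2-fold. The single gene above 0 was 1 of the 2 S27e genes (COG2051), at 0.05 (-0.02 to 0.12), and the other S27e gene was at -0.29. Ribosome biogenesis factors did not follow. Their median was 0.09 over 22 genes (percentile 74.1), with 4 at least 2-fold higher, among them a Rio1-type kinase (COG1718) at 1.96 (1.77 to 2.16) and the Emg1 methyltransferase (COG1756) at 1.72 (1.51 to 1.94). The histone list had a median of -0.47 (interval -1.44 to -0.15, percentile 1.3), 9 of 9 genes below 0, or 6 with library totals, and 4 at least 2-fold lower. The H3 and H4 group (COG2036), which also holds related histone-fold proteins, gave 6 of the 9 genes. A gene of that group reached -1.49 (-1.54 to -1.44) and a histone H2A (COG5262) -1.44 (-1.51 to -1.37). DNA replication, repair and cell cycle genes had a median of 0.17 over 54 genes (percentile 97.3). Subunits of the MCM helicase (COG1241) were its highest members at 1.66 (1.57 to 1.75) and 1.37 (1.28 to 1.46), and a MutL mismatch repair gene (COG0323) its lowest at -1.60 (-1.78 to -1.42).

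The chaperone and oxidative stress lists held some genes past 2-fold, while their medians stayed inside the range of their random lists. Among 25 chaperone genes the median was 0.06 (percentile 84.7), with 4 at least 2-fold higher and 1 lower, or 5 and 0 with library totals. An Hsp70 gene (COG0443) at 1.97 (1.84 to 2.11) and a disaggregase of the Hsp104 type (COG0542) at 1.72 (1.62 to 1.81) were highest, and another gene of that disaggregase group was lowest at -1.20 (-1.26 to -1.15). The Hsp90 gene (COG0326), named for its abundance after its value was seen, stood at 1.17 (1.15 to 1.18), with 43052 untreated and 104310 caffeine-treated counts. Oxidative stress defence had a median of 0.07 over 32 genes (percentile 86.4), of which 1 was also in another list. Of these genes 3 were at least 2-fold higher and 2 lower, or 6 and 0 with library totals. A glutathione S-transferase (COG0625) stood at 1.46 (1.38 to 1.54) and a manganese superoxide dismutase (COG0605) at 1.35 (1.30 to 1.41). Iron, copper and phosphate uptake had a median of -0.60 over 10 genes (interval -1.32 to 0.15, percentile 0.2), with 2 genes at least 2-fold lower, 1 at least 2-fold higher and 7 within 2-fold. A multicopper oxidase (COG2132), from a group used in high-affinity iron uptake, stood at -1.45 (-1.51 to -1.38), while a high-affinity iron permease (COG0672) stood at 1.10 (1.07 to 1.14). Sterol synthesis had a median of -0.06 over 18 genes (percentile 57.6), with 10 genes below 0, or 8 with library totals. Of the 18 genes 1 was at least 2-fold higher and 3 at least 2-fold lower. Its abundant cytochrome P450 gene (COG2124) was at -2.22 (-2.25 to -2.19) and a sterol desaturase (COG3000) at -2.26 (-2.31 to -2.20). The 3 genes of COG2124 ranged from -2.22 to 1.42. Medians of the proteasome, translation factors and aminoacyl-tRNA synthetases were -0.07, -0.12 and -0.11, all inside the range of their random lists, and turned positive with library totals. RNA polymerase subunits had a median of 0.18, the RNA exosome 0.35, trehalose and glycogen metabolism 0.08, and major facilitator, multidrug and ABC transporters 0.01, all inside as well. Also inside were the vacuolar proton ATPase at -0.20, fatty acid synthesis at -0.21, purine synthesis at -0.14, ubiquitin conjugation at -0.09 and mitochondrial-type ribosomal proteins at -0.28.

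**Figure D2:**
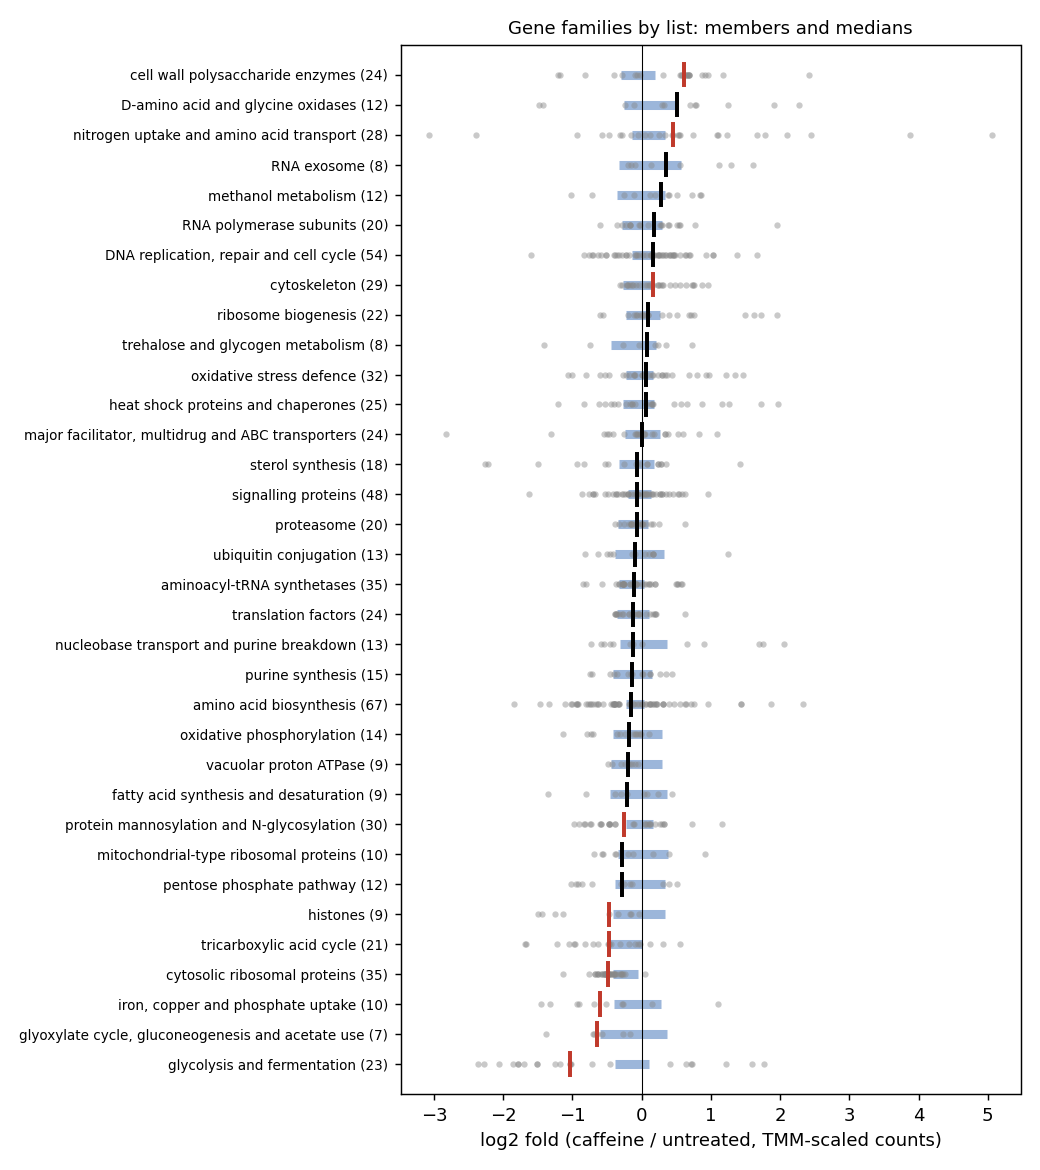
For each of 34 lists, grey points give the log2 fold of caffeine-treated over untreated of each member, the vertical bar their median and the blue band the central 95% of medians of 10000 random lists matched on expression; red bars mark the 10 medians outside that band and numbers in brackets the genes per list. The median of glycolysis and fermentation, -1.04, lies lowest and that of cell wall polysaccharide enzymes, 0.61, highest.

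The highest single fold among genes with a COG of known function belonged to a class III aminotransferase of the BioA type (COG0161), with 53 untreated and 5140 caffeine-treated counts and a log2 fold of 6.49 (6.10 to 6.91). Amidases (COG0154) stood at 5.45 (4.67 to 6.37) and 3.15 (2.94 to 3.36), an amidohydrolase of the imidazolonepropionase type (COG1228) at 3.96 (3.41 to 4.57) and an arginase or agmatinase gene (COG0010) at 3.25 (2.69 to 3.86). An ornithine aminotransferase type gene (COG4992) went from 14 to 242 counts, with a counting interval of 9.37- to 29.8-fold for its higher level. Transport was represented by a purine nucleoside permease (COG5042) at 3.83 (3.74 to 3.92) and by the only potassium transporter of the Kup type (COG3158), which went from 195 to 2148 scaled CPM, a log2 fold of 3.46 (3.41 to 3.51). A zinc-dependent dehydrogenase (COG1063) at 4.92 (4.13 to 5.84) and an esterase (COG0657) at 4.01 (3.46 to 4.62) complete the 12 highest. Several of these rest on few untreated counts, 13 for the higher amidase and for the dehydrogenase with the aminotransferase of COG4992 close to them. With 5 CPM added to both libraries the aminotransferase of COG0161 stood at 5.10, the higher amidase at 2.69, the dehydrogenase at 2.24, the esterase at 2.21, the amidohydrolase at 2.17, the aminotransferase of COG4992 at 1.61 and the arginase or agmatinase gene at 1.60.

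The lowest folds among genes with a COG outside the categories of unknown or only general function began with a DNA topoisomerase VI type gene (COG1697) at -3.36 (-3.68 to -3.05), from the group of the meiotic enzyme Spo11. A gene of an acetate transporter type group (COG1584), placed in the category of unknown function and picked after its value was seen, lay lower at -3.82 (-3.91 to -3.74). Next to the permease, symporter, hexokinase, phosphofructokinase and sterol desaturase already given came a major facilitator permease (COG0477) at -2.82 (-3.25 to -2.42). A short-chain dehydrogenase (COG1028) was 7.26-fold lower, with a counting interval of 6.62- to 7.98-fold, and a flavin-dependent monooxygenase (COG0654) 6.31-fold lower, with an interval of 5.01- to 8.03-fold. Another dehydrogenase of COG1063, the group that also held 1 of the highest genes, stood at -2.62 (-2.70 to -2.54), and a prohibitin or stomatin type gene (COG0330) at -2.53 (-2.68 to -2.37). Coproporphyrinogen oxidase (COG0408), an oxygen-dependent enzyme of heme synthesis, was at -2.26 (-2.33 to -2.19). With 5 CPM added the topoisomerase type gene stood at -2.47, above the permease of COG0833 at -2.95 and the short-chain dehydrogenase at -2.65, the major facilitator permease at -1.72 and the monooxygenase at -1.81.

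Of the 346 genes at least 2-fold higher, 171 (49.4%) carried a COG and 32 (9.2%) neither a COG nor a NOG identifier, against 44.8% and 11.3% of all compared genes. Of the 256 lower genes, 119 (46.5%) carried a COG and 41 neither. The highest of the genes without a COG was HPODL_03011, with 662 untreated and 38374 caffeine-treated counts, a log2 fold of 5.75 (5.64 to 5.86). HPODL_01681 followed at 4.87 (4.58 to 5.18). The lowest were HPODL_03366 at -4.55 (-5.02 to -4.12) and HPODL_01783 at -4.18 (-4.48 to -3.90). With 5 CPM added HPODL_01681 stood at 3.97, and the order of the lowest pair turned, with HPODL_03366 at -3.03 and HPODL_01783 at -3.32.

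By broad category, carbohydrate transport and metabolism was lowest, with a median of -0.22 over 178 genes, below all random lists. In it 33 genes were at least 2-fold lower against 15 higher, or 25 against 21 with library totals. Of the 178 genes 118 lay below 0, or 89 with library totals. Translation and ribosome structure had a median of -0.15 over 330 genes (percentile 0.2), yet 26 of its genes were at least 2-fold higher and 3 lower, and the 202 genes below 0 became 146 with library totals. RNA processing stood at 0.25 over 79 genes (percentile 99.6), replication and repair at 0.14 over 171 (percentile 99.2) and the cytoskeleton at 0.15 over 72 (percentile 99.1). Amino acid transport and metabolism had a median of 0.02 over 178 genes (percentile 85.3), with 29 genes at least 2-fold higher and 13 lower. Genes of general function prediction only stood at 0.10 over 489 genes (percentile 99.8). Of 23 categories, 4 were above the central 95% of their random lists and 2 below it.

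The 20 most abundant genes of each library, ranked separately in each, took 16.33% of the counts (exact 95% interval 16.32 to 16.35) in the untreated library and 12.66% (12.64 to 12.67) in the caffeine-treated one. Across the 4861 genes, log2 folds from the deposited TMM and RLE tables had a correlation of 1.00 and a slope of 1.00 with those computed from the counts. Folds from the deposited RPKM table had a correlation of 1.00 and a slope of 1.00 as well, with a median offset of 0.21. Genes are not independent replicates, and these values only describe how the tables relate.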

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

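No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out in turn. The counts of 346 higher and 256 lower genes stayed within 1.5 times under DESeq2 factors, upper-quartile scaling, the deposited RLE and TMM tables, no filter, 5 CPM added, the interval rule and without the 20 most abundant genes, where they ranged from 244 to 411 and from 210 to 317. The higher count went to 564 with library totals and to 553 with the deposited RPKM table, where lower genes were 175 and 178, because both lack a composition scaling and add 0.22 and 0.21 to the median log2 fold; the higher share was then 76.3% and 75.6%. With a filter of 50 CPM fewer genes entered and 183 were higher and 179 lower. List medians were computed under library totals, DESeq2 factors, upper-quartile scaling, the RPKM table, no filter and 5 CPM added, and under these no list outside its random lists turned in sign. The same offset moved 11 list medians with library totals beyond their 95% order-statistic interval: oxidative phosphorylation to 0.03, vacuolar proton ATPase to 0.02, cytosolic ribosomal proteins to -0.26, translation factors to 0.10, aminoacyl-tRNA synthetases to 0.10, RNA polymerase subunits to 0.39, cell wall polysaccharide enzymes to 0.83, proteasome to 0.15, signalling proteins to 0.16, amino acid biosynthesis to 0.05 and DNA replication, repair and cell cycle to 0.38. The deposited RPKM values moved 9, to 0.02 for oxidative phosphorylation, 0.01 for the vacuolar ATPase, -0.30 for ribosomal proteins, 0.09 for translation factors, 0.10 for synthetases, 0.82 for cell wall enzymes, 0.14 for the proteasome, 0.15 for signalling and 0.38 for DNA replication. Random lists not matched on expression put 3 lists on the other side of the limits: the cytoskeleton went inside, at percentile 88.9, while amino acid biosynthesis (0.7) and D-amino acid oxidases (99.5) went outside. Of 28 genes named as highest or lowest none turned in sign; library totals and the RPKM table moved 13 each beyond their counting intervals, upper-quartile scaling 2, DESeq2 factors 0, and 5 CPM added to both libraries 22. Depth limits the folds of genes with few counts in 1 library, such as the amidase with 13 untreated counts.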

Other observations

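Tests of counting error, of abundance, of glucose exhaustion and of TORC1 in this part were chosen after the values they measure had been seen, as were the families named next, the check without chromosome VII and the test of lower genes at chromosome ends, while the other tests on neighbouring genes were set before their results. The abundance and glucose tests replaced earlier ones on list medians, which proved too imprecise or moved with the scaling. Both tests on chromosome ends were first read without the check on chromosome VII, and read so they favoured position over gene level; the stricter reading given here was adopted once that check was seen.

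Among 121 COG families with at least 4 compared genes, 15 had a median above the central 95% of matched random lists and 4 a median below it. Chance would give about 6.1 outside if genes varied independently, which neighbouring genes did not. The 15 include the D-amino acid oxidase group (COG0665) at percentile 97.6 in this draw, the same 12 genes that were placed inside as a list. Among the high families were arginases and agmatinases (COG0010) with a median log2 fold of 1.71 over 4 genes, RidA-type imine deaminases (COG0251) with 1.78 over 4, aromatic-type aminotransferases (COG1167) with 1.16 over 4 and amidases (COG0154) with 1.05 over 7, of which 4 were at least 2-fold higher and 1 at least 2-fold lower. Of the RidA-type genes, 2 lie in the single run at the end of chromosome III given below. All 6 MCM helicase genes (COG1241) were above 0, between 0.40 and 1.66, as were 5 Sir2-type deacetylases (COG0846), between 0.50 and 1.06, and 4 tRNA-dihydrouridine synthases (COG0042), between 0.31 and 1.60. Aldehyde dehydrogenases (COG1012) had a median of 0.73 over 8 genes, aldo/keto reductases (COG0656) 0.64 over 10, and zinc-dependent alcohol dehydrogenases (COG1064) 0.72 over 6. On the low side stood sterol desaturases (COG3000) with -1.22 over 4 genes, protein O-mannosyltransferases (COG1928) with -0.74 over 5 and mannosyltransferases of the Ktr type (COG5020) with -0.39 over 9. The 4 dehydrogenases of COG1063 parted, with 3 at least 2-fold lower and 1 at 4.92.

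The low glycolytic transcripts were open to a technical reading, since log2 folds across all genes correlate with mean level (r = -0.22 and rho = -0.25, across genes, which are not independent replicates). A lower share of abundant transcripts in general, or their scaling, is argued against by the 14 of 23 members at least 2-fold lower, where the highest of 10000 lists matched in 50 bins of expression held 10; among the 100 most abundant genes, 9 of 10 in the list and 5 of 90 outside it were that low. Exhaustion of glucose during the treatment would put genes of the glyoxylate cycle and gluconeogenesis at least 2-fold higher, but the highest of these had a log2 fold of -0.17, and no upper counting bound passed 0.10 under any scaling. The criteria for abundance and for glucose were set after these values had been seen, so that neither is an independent test. The added time in culture without caffeine cannot be told apart from the drug, since 0 untreated libraries labelled as time-matched were compared. An effect of caffeine on glycolytic transcription may therefore be stated only as a hypothesis.

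Amino group and ammonium genes among the highest folds, a grouping made after the folds were seen and not tested for enrichment, may reflect a relief of nitrogen repression, which TORC1 inhibition produces in budding yeast. Counting error at low untreated counts is argued against as the only source, as the smallest lower bound among the 12 highest named genes was 2.69 on the log2 scale. These intervals were not widened for picking the highest of 4861 genes, so that the folds may be overstated. Lower TORC1 activity would also be expected to lower ribosome biogenesis transcripts, and these had a median of 0.09 with a 95% order-statistic interval of -0.07 to 0.71; with library totals the interval was 0.15 to 0.93, wholly above 0 and against that explanation, so that the answer depends on the scaling and stays open. The listed cytosolic ribosomal protein genes, with a median of -0.48, would go with it. Elapsed time and use of nitrogen sources in the medium stay open for this pattern too.

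Neighbouring genes had similar folds. Adjacent genes showed r = 0.20 over 4527 pairs (rho = 0.22, one-sided permutation p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.00024 by Benjamini-Hochberg over 12 such correlations). At the end of chromosome III, 9 of 10 consecutive compared genes were at least 2-fold higher, among them genes of COG1063, COG4992, COG0657, COG3616 and, with 2 genes, COG0251. The highest of 2000 permutations held 7, while the best run of lower genes held 5, which 295 of 2000 permutations reached. Some genes of the higher run passed the 10 CPM filter only through the caffeine-treated library, such as that of COG1063 at 0.7 untreated and 22.2 caffeine-treated scaled CPM. Genes under the filter were left out, so that the run need not be contiguous, and the permutations do not address this selection. Reads spilling over between adjacent genes cannot alone give the correlation, because r was 0.23 for 567 pairs at least 500 bases apart (permutation p = 0.0001, adjusted 0.00024). At a distance of 3 genes r was 0.032 (permutation p = 0.013, adjusted 0.017), just past the permuted upper limit of 0.029. Nor can reads shared between copies of one family alone give it, since r was 0.206 without pairs of the same COG or NOG. Position near chromosome ends may add to it: at the 12 other ends, 15.8% of the 240 outermost genes were at least 2-fold higher against 6.4% elsewhere (rotation permutation p = 0.0004), and 0.03% of random sets matched on expression held as many, while 10.8% were at least 2-fold lower against 5.0% elsewhere (0.05% of matched sets). Without chromosome VII, 24 of 200 end genes were that high and 11.85% of matched sets held as many. Position and the lower levels of the genes near chromosome ends can therefore not be told apart for the higher genes. Of the genes at least 2-fold lower, 24 of 200 remained and 0.04% of matched sets held as many. That check could hardly change their count, as each end of chromosome VII held 1 of them. The ends of chromosome I held 4 and 6 and were not left out. Matched sets also drew genes independently, which neighbouring genes were not, so that gene level stays open here too. Adjacent genes away from the ends still had r = 0.17, and no biological explanation was tested.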
